A study of Mus musculus with 10 samples.

How the data were processed

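Gene expression was measured by RNA sequencing in 10 libraries of cultured mouse cells. Per the labels' protocols, embryonic stem cells (ESCs) of the R1 and E14 lines and of an Otx2-/- line, all of 129SV origin, were grown in serum-free medium with LIF, the MEK inhibitor PD0325901 at 0.8 µM and the GSK3 inhibitor CHIR99021 at 3.3 µM. Epiblast-like cells (EpiLCs) were made from them in 48 h with bFGF and knockout serum replacement, and 1 R1 library had activin A at 20 ng/ml in addition. The labels do not say whether the E14 and Otx2-/- EpiLCs had activin A. Another pair of ESC libraries came from Otx2-/- cells with a tetON Otx2 transgene, grown without or with doxycycline (dox), whose dose and duration are not given in the sources used here. Polyadenylated RNA was selected, and libraries were primed with random hexamers and sequenced on an Illumina Genome Analyzer, per the labels' protocols. No step that marks the strand is described, so reads of overlapping and antisense genes cannot be told apart.

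The deposited values are FPKM per gene, made with TopHat and Cufflinks on the mouse genome build mm9, per the submitters' processing notes. Tool versions, the gene annotation and the settings are not given in the sources used here. Each of the 10 tables held 23112 entries. Of these, 17 were exact repeats and were dropped, and 228 further entries shared a symbol with another and were summed, which left 22867 symbols. Entries carrying several symbols numbered 191, and 276 entries spanned under 200 bp, most of them small RNAs. Coordinates are those of the deposited tables on mm9, counted from 1. FPKM values are not counts, so no count model was used, although the plan made before the data were examined had count-based tests ready in case the tables held counts.

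Depth was approximated from the values. In olfactory receptor genes, which have transcripts of about 1 kb and hardly any reads in these cells, the lowest values above 0 step by what 1 fragment is worth. The 25th percentile of those values, which rested on between 36 and 92 entries above 0 per library out of 969, gave between 6.2M and 20.8M fragments per library. These figures are rough, since the annotated transcript length was not used.

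An exact 0 was listed for abundant housekeeping genes in single libraries. An entry listed at 0 in a library while its median over all libraries was at least 5 FPKM is therefore described only by its values. Small RNAs (microRNA, snoRNA and similar symbols) selected as polyadenylated RNA carry values that are hard to interpret, and calls among them are counted separately. The class was set by symbol. It also takes in Snhg host genes and entries that carry a small RNA symbol beside that of another gene.

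Differences were tested with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, two-sided) on log2(FPKM + 1), for genes with a mean of at least 1 FPKM, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on this scale understates the change of genes with low FPKM. EpiLCs were compared with ESCs over 3 and 3 libraries of R1 and E14, with the line as a covariate. The single Otx2-/- ESC and EpiLC libraries were each compared with the 3 R1 and E14 libraries of the same state in a fit of 8 libraries, in which the lone library is assumed to vary like the others. The difference in differentiation response between Otx2-/- and the other lines, and between E14 and R1, was tested as an interaction. Per the labels' protocols the ESC and EpiLC cultures were independent biological replicates. The p-values measure the spread between these few libraries, which in EpiLC also includes activin A. In the comparisons of Otx2-/- with R1 and E14 of the same state, which had no line term, it also includes level differences between the lines.

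Comparisons of 1 library with 1 have no replicate check and no p-value. In them a gene was counted when its log2 ratio of (FPKM + 1) was at least 1 in size and it reached 5 FPKM in at least 1 of the pair. The 23 gene lists, with 305 entries, were fixed before the data were examined. In tested comparisons they were summarised by counts of members and by camera with an inter-gene correlation of 0.01, with an estimated correlation as the alternative. Fry, a rotation test of whether the genes of a list changed in a common direction, was planned beside camera. Camera compares a list with other genes, and fry compares it with no change. In pairs of libraries they were summarised by the median log2 ratio and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. That median was taken over list members with a mean of at least 1 FPKM in the pair.

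Genes named were chosen by a rule fixed before the data were examined. It took Otx2, 10 marker genes, the 8 largest changes each way among genes that passed the test and separated the groups completely, and up to 4 members of each list described. Small RNAs and multi-copy families were left out of the 8, for example 18 of 2463 candidates in EpiLC against ESC. Genes listed at 0 in a library compared (30 of those candidates) were passed over as well, a choice made after seeing the data. Pecam1, Eomes, the genes named for partial differentiation, the Zscan4 copies in the Otx2-/- comparisons and genes listed at 0 were named in addition.

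The limma tests were run on simulated data with 100 genes changed 2-fold and 100 changed 4-fold; camera, the size rule and the list percentiles were also run on simulated changes, and fry was not. In EpiLC against ESC, 33% of the 2-fold and 89% of the 4-fold changes were recovered among 12244 genes. In Otx2-/- EpiLC against R1 and E14 EpiLC the shares were 7% and 63%, and in ESC 4% and 73%, among 12271 genes. False calls among genes left as they were numbered 1 in EpiLC against ESC, 5 in Otx2-/- EpiLC and 4 in Otx2-/- ESC. Both interactions recovered 0% at either size, so a low count of calls there does not show that responses were alike.

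Alternatives covered the pseudocount, the filter on low values, quantile and median-ratio scaling, the variance trend, the line term, the libraries fitted, and leaving out each library in turn. Alternatives without small RNAs and entries listed at 0, list counts without R1 ESC replicate 1, and a correlation over the genes that differed between the R1 ESC replicates, were added after seeing the data. Transcript length and GC content, used in a single check, came from a GENCODE annotation matched by symbol. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.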

Results

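The series asked which genes change when mouse ESCs become EpiLCs, and how loss or overexpression of the homeobox gene Otx2 affects this. ESCs held with MEK and GSK3 inhibitors and LIF stand for naive pluripotency, and EpiLCs for the early post-implantation epiblast. There were 2 libraries of R1 ESC, 1 of E14 ESC and 1 of Otx2-/- ESC. EpiLC libraries numbered 2 for R1 (1 without and 1 with activin A), 1 for E14 and 1 for Otx2-/-, and the labels do not say whether these last had activin A. The Otx2-/- line with a dox-inducible Otx2 transgene gave 1 ESC library without and 1 with dox. Approximate depth was lowest in E14 EpiLC at 6.2M fragments and highest in Otx2-/- ESC at 20.8M. At 5 FPKM, a 2 kb transcript then rested on between 62 and 210 fragments. FPKM summed to between 585995 and 680016 per library, and between 11410 and 12134 entries reached 1 FPKM.

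Otx2 lies on chromosome 14 at 49277859 to 49282547. Its level was 5.72 and 9.09 FPKM in the R1 ESC replicates and 3.96 in E14 ESC, with a mean of 6.26 ± 2.61 (SD, n = 3). In EpiLC it was 107 FPKM without and 151 with activin A in R1, and 39.9 in E14, with a mean of 99.1 ± 55.8 (SD, n = 3). The Otx2-/- libraries had 7.85 FPKM in ESC and 15.8 in EpiLC. Without dox the transgenic Otx2-/- ESCs had 45.8 FPKM, and with dox 1059.3. The labels do not say which part of the gene is deleted, and reads from remaining exons count, so the value in Otx2-/- ESC neither checks nor contradicts its label.

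**Figure D1:**
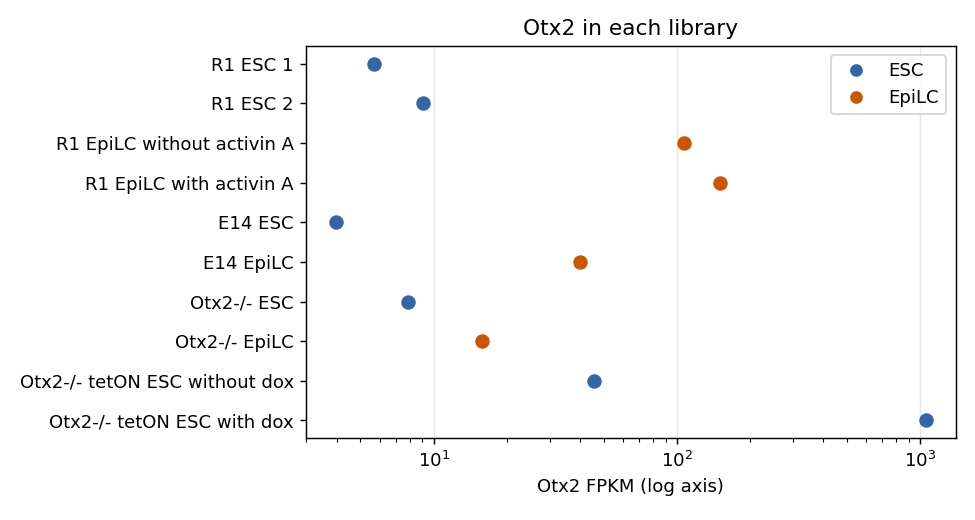
Otx2 in each of the 10 libraries, as FPKM on a log axis, with ESC and EpiLC libraries in different colours. R1 and E14 EpiLC lay between 39.9 and 151 FPKM, Otx2-/- EpiLC at 15.8, and transgenic Otx2-/- ESC with dox at 1059.3.

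On conversion to EpiLC the transcription factors of naive pluripotency fell and genes of the post-implantation epiblast rose. Klf4, a naive pluripotency factor on chromosome 4 at 55540009 to 55545347, went from 87.7 ± 13.7 FPKM in ESC to 0.944 ± 0.127 in EpiLC (SD, n = 3 each), a log2 fold change of -5.50 (SE 0.17). Tfcp2l1, another naive factor, went from 153 ± 31.1 to 6.60 ± 2.70 FPKM, and Tbx3 fell by 5.10 on the log2 scale. Fgf5, the growth factor that marks the epiblast, on chromosome 5 at 98683203 to 98706049, rose from 0.655 ± 0.134 to 31.5 ± 3.83 FPKM (log2 fold change 4.29, SE 0.15, limma adjusted p = 0.000793). Pou3f1, a POU transcription factor of the epiblast, rose from 1.30 ± 0.37 to 61.0 ± 16.6 FPKM. Otx2 itself rose by 3.65 (SE 0.29, limma adjusted p = 0.00298).

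Among genes with no value of 0 in these 6 libraries, the largest rise was that of Car4, a membrane-bound carbonic anhydrase, from 0.217 ± 0.098 to 64.1 ± 11.9 FPKM (log2 fold change 5.73, SE 0.18). It was followed by the iron exporter Slc40a1 (4.76), Pou3f1 (4.73), Cthrc1 (4.50), the tight junction protein gene Cldn7 (4.39), the peptide hormone gene Adm (4.36), Fgf5 and the chemokine gene Cxcl12 (4.26). After Klf4, the largest decreases among them were those of the junction protein gene Jam2 (-5.41), Tbx3, Tcl1 (-4.70), the water channel gene Aqp3 (-4.67), Ntn1 (-4.61), the threonine dehydrogenase gene Tdh (-4.53) and Tfcp2l1 (-4.39). Also called were 2610528J11Rik, listed at 0 in R1 ESC replicate 2 and with 39.1 FPKM or more in EpiLC, and 2210409E12Rik, listed at 0 in E14 EpiLC and with 56.4 FPKM or more in ESC. Among the other markers, Esrrb fell by 3.55, Nanog by 2.01 and Pou5f1, which encodes Oct4, by 0.87, from 974 ± 38.4 to 534 ± 12.5 FPKM. The de novo DNA methyltransferase gene Dnmt3b rose by 2.37. Sox2 had a log2 fold change of -1.04 that did not pass (limma adjusted p = 0.0575), Lefty2 lay at -0.08 (adjusted p = 0.938), and T was too low to be tested.

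Of 18 naive pluripotency genes, 16 fell and 1 rose, counted over all genes and adjusted over the list alone. Dppa3 rose by 1.07 and Pecam1, at -0.53, did not pass. Camera placed the list below other genes (adjusted p = 2.55e-11; adjusted p = 0.486 with an estimated correlation). Of 20 genes of the primed and formative epiblast, 13 rose and 0 fell, and 14 rose adjusted over the list alone (camera adjusted p = 1.01e-08; adjusted p = 0.486 with an estimated correlation). Besides Pou3f1 and Fgf5 these included Krt18 (3.86), Dnmt3a (2.79) and Sall2 (2.65). Wnt8a, also called, had at most 1.25 FPKM in ESC, where R1 replicate 2 listed it at 0, and between 7.57 and 29.1 in EpiLC. Among 14 general pluripotency genes 1 rose, Utf1 (0.72), and 3 fell, led by Sall4 (-1.58); adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.253).

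Cholesterol synthesis genes rose together: 10 of 13 rose and 0 fell, with 12 rising adjusted over the list alone (camera adjusted p = 1.46e-07; adjusted p = 0.486 with an estimated correlation). Dhcr7, the enzyme of the final reduction to cholesterol, went from 17.8 ± 2.89 to 54.2 ± 10.2 FPKM, and Insig1, a sterol-sensing regulator, rose by 1.51. Of 18 genes of mitochondrial respiration 4 fell, among them Cox6a1 (-0.81), and 0 rose; 5 fell adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.612 with an estimated correlation). Glycolysis genes showed 1 rise, Pdk1 (0.97), and 2 decreases, Pfkp (-1.88) and Hk2 (-1.17), among 16. Of 9 genes of the DNA methylation machinery, Dnmt3a and Dnmt3b rose, while the dioxygenase gene Tet2 (-1.73) and Uhrf1 (-0.68) fell. Adjusted over the list alone, 2 of them rose and 5 fell; the median was -0.37, the mean 0.18 and camera's direction down.

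Single targets of signalling pathways passed, although camera placed none of these 4 lists apart. Of 11 ERK targets, 3 rose, namely the phosphatase genes Dusp4 (2.82) and Dusp5 (1.26) and Ier3 (2.45), and 0 fell; adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.0963). The BMP targets Id3 (-2.72), Id4 (-2.37), Id1 (-2.12) and Msx2 (-1.43) fell, 4 of 7, also adjusted over the list alone (camera adjusted p = 0.151). Among 9 Nodal and Activin targets 3 rose, among them Skil (2.56) and Bcar3 (0.97), and Gdf3 (-1.34) fell, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.434). Of 8 Wnt targets, Tcf7 (1.31) rose and Notum (-4.19) and Cdx1 (-4.14) fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.306). Of 13 epithelial and mesenchymal genes 6 rose, among them the epithelial genes Krt18, Cldn3 (2.65) and Cldn6 (2.61), and 3 fell, among them the mesenchymal filament gene Vim (-2.49); adjusted over the list alone 7 rose and 3 fell.

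Markers of other lineages were mostly low. Of 13 primitive streak genes only 3 were expressed enough to test, and none passed in limma (1 rose and 1 fell without R1 ESC replicate 1). Of 5 neural genes tested, Ncan rose (0.92) and Tubb3 (-3.09) and Sox21 (-1.71) fell. Of 4 anterior patterning genes 3 fell, Fzd5 (-2.49), Sfrp1 (-2.10) and Shisa2, also adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.486 with an estimated correlation). Primitive endoderm genes split, with Lamb1 (2.43) and Dab2 (1.48) rising and Lama1 (-2.55) and Sparc (-0.84) falling among 6. Krt7 (1.83) rose among 4 trophoblast genes, and Tagln (1.00) rose and Timp1 (-1.76) fell among 4 fibroblast genes. Of 12 germline genes 3 rose, led by Mael (2.77), and Rpl10l fell (-2.71). Of 11 p53 and stress genes Btg2 rose (1.49) and 3 fell, among them Cdkn1a (-1.14); without R1 ESC replicate 1, 4 rose and 4 fell. None of 14 cell cycle genes passed in limma, over all genes or adjusted over the list alone. The same held for the 4 genes tested from the list of Y-linked genes and Xist. Of the 2-cell-like genes, near-identical copies whose values are uncertain, Zscan4d fell (-1.05), and all 3 tested fell adjusted over the list alone.

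In total 1191 genes rose and 1293 fell of 12244 tested (limma, adjusted p under 0.05), 754 and 673 of them by 2-fold or more, and 4509 had an unadjusted p under 0.05. Small RNAs made up 8 of these calls and entries listed at 0 another 8. The 2484 calls numbered 4118 without R1 ESC replicate 1, 844 without E14 ESC, 773 without E14 EpiLC, 598 without R1 EpiLC with activin A and 398 without R1 EpiLC lacking it, and no call changed sign. Fry, which tests a list against no change, called the same 5 lists as camera, with adjusted p = 0.00393 for naive and primed genes, 0.00928 for anterior patterning and 0.0154 for mitochondrial respiration and cholesterol synthesis. Without R1 ESC replicate 1, 17 naive genes fell, 15 primed genes rose, 13 of 13 cholesterol genes rose, 6 ERK targets rose and 1 fell, 6 mitochondrial genes fell and 3 of 6 BMP targets fell. In the same fit, 6 germline genes rose and 2 fell, 3 general pluripotency genes rose and 5 fell, 3 of 5 fibroblast genes rose and 1 fell, and 2 primitive endoderm genes rose and 4 fell. Wnt targets had 2 rising and 3 falling of 7, 3 of the 2-cell-like genes fell, 1 trophoblast gene rose and 1 fell of 5, and 1 cell cycle gene rose.

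**Figure D2:**
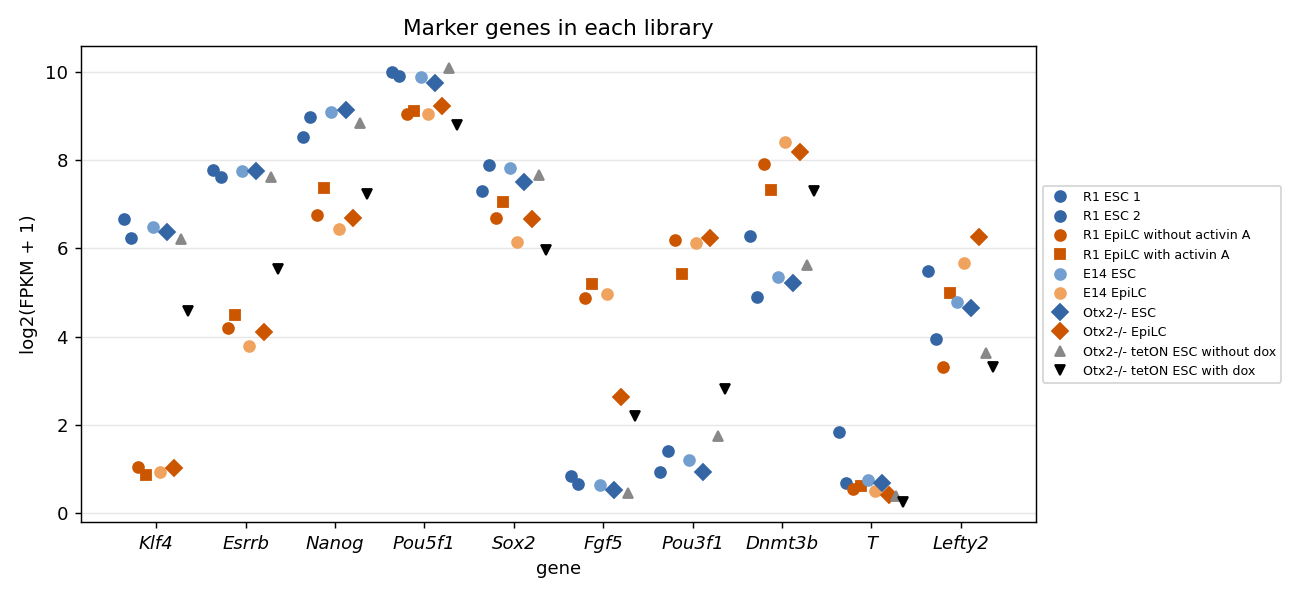
The 10 marker genes in each library, as log2(FPKM + 1), with a symbol per library. Klf4 and Esrrb are high in the ESC libraries and low in EpiLC, and Fgf5 in Otx2-/- EpiLC, at 5.18 FPKM, lies below the other EpiLC libraries, whose mean is 31.5.

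R1 ESC replicate 1 stood apart from the other ESC libraries. Trh, which encodes thyrotropin-releasing hormone, had 764 FPKM in it and 27.0 in replicate 2, and Myc had 28.7 and 2.29. Vegfa, an angiogenic factor, had 2.22 and 30.9. Replicate 2 was below replicate 1 in Wnt targets (median log2 ratio -0.85, percentile 0), p53 and stress genes (-0.78, percentile 0.1), BMP targets (-0.68, percentile 0.3) and ERK targets (-0.67, percentile 0.5). It was also below in epithelial and mesenchymal genes (-0.57, percentile 0.8) and in the primitive streak list (-0.92, percentile 0.2, over 4 expressed genes), where Eomes had 3.18 against 9.31 FPKM. It was above replicate 1 in glycolysis (0.56) and germline genes (0.91, percentile 100 for both). Naive pluripotency genes differed little (-0.12). By the size rule 1053 genes differed, 496 higher and 557 lower in replicate 2, and 880 without small RNAs and entries listed at 0. The median gene lay at -0.22; median-ratio scaling turned the split to 633 higher and 346 lower, and quantile scaling to 580 and 360. The pairs of ESC libraries without replicate 1 and without dox differed in between 55 and 153 genes under that same restriction.

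**Figure D3:**
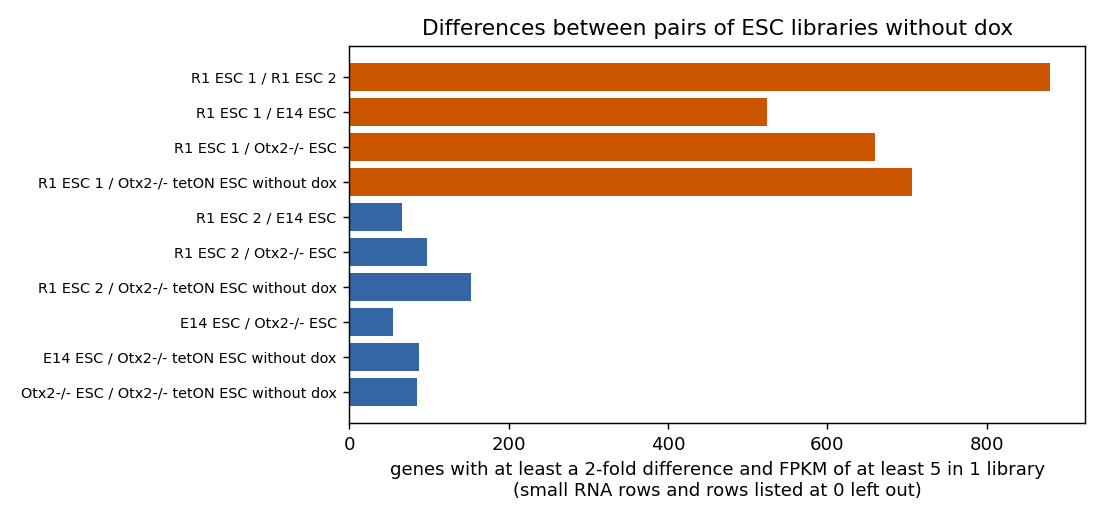
Number of genes that differed at least 2-fold, with 5 FPKM or more in 1 library, for each pair of ESC libraries without dox; small RNAs and entries listed at 0 are left out. Pairs with R1 ESC replicate 1 gave between 524 and 880 genes, and the others between 55 and 153.

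E14, which supplies 2 of the 6 libraries of that fit, was also compared alone. In E14 EpiLC, Car4 (log2 ratio 5.58), Pou3f1 (4.91), Tmem54 (4.75) and Wt1 (4.64) were higher than in E14 ESC, and Aqp3 (-6.08), Jam2 (-5.96) and Klf4 (-5.55) lower. Of 17 naive genes with 5 FPKM, 17 were at least 2-fold lower (median -3.71, percentile 0), and of 19 primed genes 14 were higher (median 1.87, percentile 100). ERK targets (median 1.31), cholesterol genes (0.93) and Nodal and Activin targets (0.89, against 0.05 in the joint fit) were higher. BMP targets (-1.65) and glycolysis genes (-0.62, against -0.06) were lower. The size rule counted 640 higher and 858 lower genes, with no replicate check. Across 11936 genes, which are not independent replicates, E14 and R1 log2 ratios correlated at r = 0.768 (Spearman 0.673).

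The E14 response minus the R1 response gave 15 higher and 25 lower calls in limma, of which 33 were small RNAs and 6 were entries listed at 0. Fgf5 differed by 0.05 and Pou3f1 by 0.28, and neither passed (limma adjusted p = 0.982 and 0.935). Camera placed naive (median -0.65, adjusted p = 0.000281), glycolysis (-0.83, adjusted p = 8.53e-05) and trophoblast genes (-1.20, adjusted p = 0.00358) lower in the E14 response than in that of R1. Each had adjusted p = 0.736 with an estimated correlation, and no member of these lists passed over all genes or adjusted over the list alone. In glycolysis genes R1 ESC replicate 2 was itself above replicate 1 by a median of 0.56, against -0.12 in naive and 0.15 in trophoblast genes. Leaving out R1 ESC replicate 1 gave 80 calls, replicate 2 127, and either R1 EpiLC library 0. An unadjusted p under 0.05 was found for 380 genes in the fit of all 6 libraries.

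In EpiLC of the Otx2-/- line, Fgf5 was low: 5.18 FPKM against 31.5 ± 3.83 (SD, n = 3) in R1 and E14 EpiLC, a log2 fold change of -2.39 (SE 0.20, limma adjusted p = 0.0117). The fold stayed but the call ended without R1 EpiLC lacking activin A (-2.46, limma adjusted p = 0.0527), without E14 ESC (-2.39, 0.0546) and in a fit of EpiLC libraries alone (-2.39, 0.11). Otx2 itself had a log2 fold change of -2.38 (SE 0.74) that did not pass (limma adjusted p = 0.96). Of the 20 primed genes, Fgf5 alone fell and 0 rose, also adjusted over the list alone. Pou3f1, at 74.2 FPKM against 61.0 ± 16.6, differed by 0.32 and Dnmt3b by 0.31, and Krt18, a keratin gene, by -1.97 (SE 0.74); none of these passed. The naive genes were as low as in the other EpiLCs, with Klf4 differing by 0.06, Nanog by -0.16 and Esrrb by -0.07 and 0 of 18 passing.

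Besides Fgf5, 2 further genes with usable values passed, and both were higher. BC017158, on chromosome 7 at 135409211 to 135441645, had 190 FPKM in Otx2-/- EpiLC against 2.45 ± 1.05 (SD, n = 3; log2 fold change 5.83, SE 0.35, limma adjusted p = 0.00151). AA467197, on chromosome 2 at 122463623 to 122466812, had 51.6 FPKM and at most 0.169 in R1 and E14 EpiLC, where E14 listed it at 0. Fancd2, a DNA repair gene with between 24.1 and 27.4 FPKM in the other EpiLCs, and Kdm4a, a histone demethylase gene with between 18.1 and 20.7, were listed at 0. Nodal and Activin targets had a median of 0.51, with Lefty1 at 1.28 and Lefty2 at 1.60; none of 9 passed (camera adjusted p = 0.0231; adjusted p = 0.865 with an estimated correlation). Activin A in these cultures, not given for Otx2-/- and E14, was not separated from loss of Otx2: Lefty1 had 200 FPKM in Otx2-/- EpiLC, 140 in E14, and 111 with and 34.3 without activin A in R1. The Zscan4 copies of the 2-cell-like list rose adjusted over the list alone, 3 of 3, with Zscan4d at 1.56 (camera adjusted p = 0.000237; adjusted p = 0.722 with an estimated correlation), and 0 passed over all genes.

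In all, 17 genes were higher and 3 lower of 12271 (limma), 15 of them small RNAs, and 441 had an unadjusted p under 0.05. The simulated data of this comparison gave 5 false calls, beside 7 recovered 2-fold and 63 recovered 4-fold changes. The real fit made 20 calls, so that number does not carry over to it. How many of the 3 calls left outside small RNAs and entries listed at 0 are false is not known. Without E14 EpiLC, the shallowest library, 21 were higher and 21 lower. For Fgf5, the limma adjusted p ranged from 0.00634 to 0.11 over its alternatives.

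In the Otx2-/- ESC library, the markers lay close to their level in R1 and E14 ESC. Klf4 had 82.1 FPKM against 87.7 ± 13.7 (SD, n = 3), Nanog 562 against 470 ± 94.4 and Pou5f1 861 against 974 ± 38.4, and none of these passed. The Zscan4 copies were higher: Zscan4c had 9.26 FPKM against between 1.22 and 3.19, and Zscan4d 14.3 against between 1.54 and 3.25. All 3 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 1.47e-11; adjusted p = 0.288 with an estimated correlation). ERK targets had a median of -0.49 (camera adjusted p = 0.0363) and Wnt targets of -0.36 (adjusted p = 0.0495), with 0 members passing and adjusted p = 0.95 with an estimated correlation for both. R1 ESC replicate 1, among the controls, was itself above replicate 2 by medians of 0.67 and 0.85 in these lists.

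Limma called 11 genes higher and 6 lower there, and 132 had an unadjusted p under 0.05. The 11 were small RNAs and 5 of the lower were listed at 0 in Otx2-/- ESC, such as Hnrnpa3, which encodes an RNA-binding protein and had between 1344.8 and 1685.5 FPKM elsewhere. The remaining call, Myo5a, a myosin gene, was also listed at 0 in Otx2-/- ESC, with between 3.64 and 4.84 FPKM in R1 and E14 ESC. Without E14 EpiLC there were 26 calls in place of 17, and with the uninduced transgenic library added as an Otx2-/- ESC library 0.

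Otx2-/- cells still converted most of the programme. From Otx2-/- ESC to EpiLC, Pou3f1 (log2 ratio 5.30) and Wnt8a (4.71) were higher and Jam2 (-5.71) and Klf4 (-5.36) lower. Fgf5 went from 0.451 to 5.18 FPKM (log2 ratio 2.09) and Otx2 from 7.85 to 15.8. Of 17 naive genes with 5 FPKM 16 were at least 2-fold lower (median -3.42, percentile 0), and of 19 primed genes 15 were higher (median 2.10, percentile 100). ERK targets (1.70), Nodal and Activin targets (1.10) and cholesterol genes (1.03) were at percentile 100. Of the genes called higher in R1 and E14, 98.4% were higher here. Their median log2 ratio was 1.06, over the 1105 with a mean of at least 1 FPKM in this pair. In the R1 and E14 fit, which chose them, the median log2 fold change over all 1191 was 1.20. Of those called lower, 99.0% were lower, with medians of -0.94 here, over 1278 genes, and -1.03 in that fit, over all 1293. The size rule counted 652 higher and 790 lower genes, with no replicate check.

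In the response itself, Otx2-/- minus R1 and E14, the same pair of genes stood out. BC017158 (5.23, SE 0.28, limma adjusted p = 0.00422) and AA467197 (5.70, SE 0.34, limma adjusted p = 0.00607) were higher. Fgf5 had a difference of -2.20 (SE 0.30) that did not pass over all genes (limma adjusted p = 0.235) but fell adjusted over the list alone, 1 of 20 primed genes. The naive list had 0 calls and a median of -0.10, and Otx2 a difference of -2.73 that did not pass (limma adjusted p = 0.998). In total 22 calls were higher and 12 lower, 25 of them small RNAs and 7 listed at 0, and 212 genes had an unadjusted p under 0.05. Without R1 EpiLC lacking activin A there were 10 calls, and BC017158 was at 5.18 (adjusted p = 0.0581); there were 52 without E14 ESC and 51 without E14 EpiLC.

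Activin A in R1 EpiLC went with higher Nodal and Activin targets. Lefty1 and Lefty2, secreted Nodal antagonists, had 111 and 30.6 FPKM with activin A against 34.3 and 8.91 without it (log2 ratio 1.67 for both). Smad7, an inhibitor of the pathway, had 13.4 against 4.08 (1.51). Of 9 members 5 were at least 2-fold higher and 0 lower (median 1.13, percentile 100). Naive genes had a median of 0.29 (percentile 100) with Nanog at 0.62, and primed genes -0.13 (percentile 0.7) with Pou3f1 at -0.77. Other lists were as extreme: ERK targets (-0.24), BMP targets (-0.31) and trophoblast genes (-0.33) lay at percentile 0.1. Neural (-0.34) and primitive endoderm genes (-0.24) lay at percentile 0.4, and cell cycle genes (0.11) at 99.9. In each of these lists 0 members passed the size rule. Otx2 was higher by 0.49. Lower with activin A were the imprinted genes H19 (-2.40) and Igf2 (-1.71), the homeobox gene Gbx2 (-1.56) and the metallothionein genes Mt1 (-1.47) and Mt2 (-1.45). Some of these also differed between the R1 ESC replicates, replicate 2 against replicate 1: Gbx2 (-1.73), Mt1 (-1.54) and H19 (1.25). Igf2 (-0.46) and Mt2 (0.17) differed less there.

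The size rule counted 96 higher and 96 lower genes with activin A, and 23 and 29 without small RNAs and entries listed at 0; there is no replicate check. Among the largest changes, Apba3 (2.63), Dgcr8 (2.35), Actr5 (-3.42) and Prmt2 (-3.31) also jumped between libraries of other groups: Actr5 had 127 and 7.11 FPKM in the R1 ESC replicates.

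Dox in the transgenic Otx2-/- ESCs raised Otx2 from 45.8 to 1059.3 FPKM and went with lower pluripotency genes. The naive genes had a median log2 ratio of -1.08 (percentile 0), 10 of 18 at least 2-fold lower and 2 higher. Nr0b1 (-3.31), Tcl1 (-3.20), Esrrb (-2.10), Klf4 (-1.64) and Nanog (-1.59) were among the lower, and Dppa3 (3.40) was higher. The general pluripotency genes had a median of -0.82 (percentile 0), with Pou5f1 at -1.30 and Sox2 at -1.70. Primed genes went both ways, 6 of 11 higher and 2 lower (median 0.10, percentile 80.4): Krt18 went from 2.66 to 144 FPKM (5.31), Dnmt3a was higher by 1.80, Fgf5 by 1.76 and Dnmt3b by 1.67, while Etv4 (-2.11) and Tcf15 (-2.09) were lower. Pou3f1, at 2.38 and 6.01 FPKM, stayed far below its 61.0 in EpiLC.

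The largest changes with dox were higher Guca1a, a guanylate cyclase activator gene, from 3.14 to 315 FPKM (6.25), Hipk3 (5.73), Car4 from 0.193 to 51.3 FPKM (5.45), Krt18, Sept4 (5.09), Igfbp5 (4.62) and Susd3 (4.52). Hipk3 also varied between libraries without dox, from 2.62 to 53.9 FPKM. Hesx1, a forebrain homeobox gene, was higher by 3.56, Snai1, a repressor of epithelial genes, by 2.88 and the stress gene Atf3 by 2.62. The anterior patterning list, which holds Hesx1, had 1 of 3 members higher and 2 lower. Its median was -0.47 over 6 expressed genes (percentile 2.1), with Fzd5 at -1.70 and Sfrp1 at -1.23. Lower were Eras (-3.82), 1700097N02Rik (-3.77), the neuronal tubulin gene Tubb3 (-3.76), Tgfbi (-3.44), the ERK inhibitor gene Spry4 (-3.42), Spink3 (-3.41), Ntn1 (-3.38) and Stmn2 (-3.38). ERK targets (median -0.58, percentile 0.1; 4 of 8 at least 2-fold lower) and Nodal and Activin targets (-0.61, percentile 0.2; 2 of 8) were lower, with 0 higher. Neural genes went both ways, with 1 of 3 higher and 2 lower (median -1.43 over 6 expressed genes, percentile 0). Germline genes were higher (0.75, percentile 100), 3 of 8 at least 2-fold and 0 lower. The untreated R1 ESC replicates differed as much in germline genes (0.91) and ERK targets (-0.67). Epithelial and mesenchymal genes (0.64, percentile 100) had 5 of 13 higher and 3 lower, and primitive endoderm genes (0.86, percentile 99.8) 2 of 5 higher and 1 lower. The size rule counted 597 higher and 531 lower genes, with no replicate check. That total of 1128 stands beside 1053 between the untreated R1 ESC replicates, of which replicate 1 stood apart. Without small RNAs and entries listed at 0 the totals were 990 with dox and 880 between those replicates. Under that restriction, pairs of ESC libraries lacking replicate 1 and dox differed in between 55 and 153 genes.

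Most genes called in R1 and E14 EpiLC went the same way with dox. Of those called higher, 69.1% were higher with dox, and 221 of 1191 were at least 2-fold higher and 27 lower. Their median log2 ratio was 0.33 (percentile 100), over the 976 with a mean of at least 1 FPKM in the dox pair. Called genes near 0 in both dox libraries are thus left out of that median. Of those called lower, 73.6% were lower, with 283 of 1293 at least 2-fold lower and 35 higher. Their median was -0.35 (percentile 0), over 1280 genes by the same rule. Among genes with a mean of at least 20 FPKM the medians were 0.12 for the higher ones (221 genes) and -0.36 for the lower ones (503 genes). The pairs share no library. In the uninduced transgenic line against Otx2-/- ESC, the medians were 0.06 (percentile 99.99) and 0.01 (percentile 2.09). There 12 and 15 genes were at least 2-fold in the same direction. This pair is not a background without Otx2. The uninduced line had Otx2 at 45.8 FPKM, above the 39.9 of E14 EpiLC, against 7.85 in Otx2-/- ESC. Across 11936 genes the dox log2 ratios correlated with those of R1 at r = 0.396 (Spearman 0.36) and of E14 at 0.329 (0.223). Both lie below the correlations of Otx2-/- differentiation, 0.744 (0.651) with R1 and 0.875 (0.819) with E14.

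**Figure D4:**
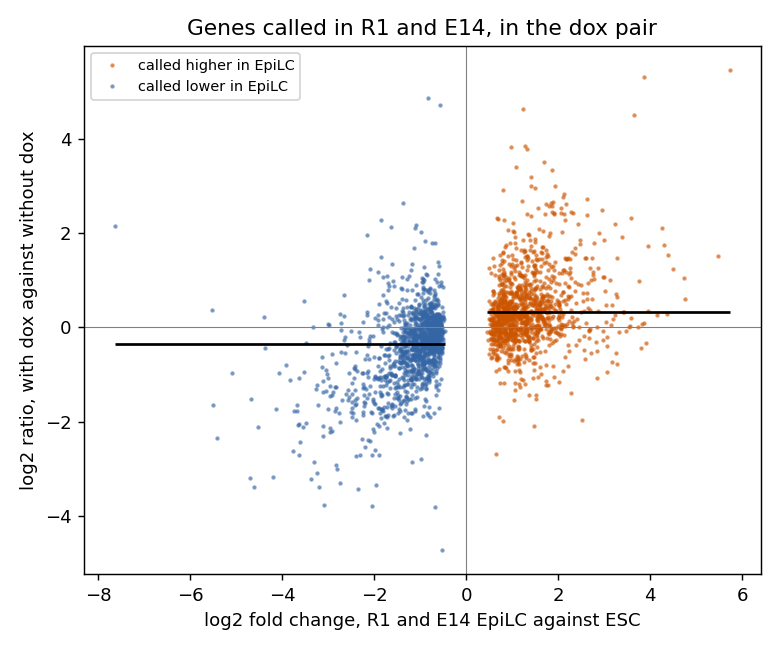
Genes called in R1 and E14, with their log2 fold change in EpiLC against ESC on the horizontal axis and their log2 ratio with against without dox on the vertical axis; a point is a gene. The horizontal lines mark the medians, 0.33 for genes called higher and -0.35 for genes called lower. They were taken over genes with a mean of at least 1 FPKM in the dox pair, while all called genes are drawn. At a mean of at least 20 FPKM the medians were 0.12 and -0.36.

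Without dox, the transgenic line differed from Otx2-/- ESC in few genes. Otx2 was higher by 2.40, the keratin gene Krt19 by 3.12, the cytokine gene Csf3 by 2.83, Utf1 by 1.62 and Dppa3 by 1.51, and Lefty1 was lower by a log2 ratio of -1.27. BMP targets had a median of 0.61 (percentile 100) and naive genes of -0.07 (percentile 2.7). The size rule counted 120 higher and 122 lower genes, and 56 and 29 without small RNAs and entries listed at 0, with no replicate check.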

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

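The search for further libraries without Otx2 was chosen after the calls were seen, and so was leaving out small RNAs and entries listed at 0.

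The differentiation response of Otx2-/- cells differed from that of R1 and E14 in 34 genes by limma's interaction test, which is what brought it here. The E14 response differed from the R1 response in 40 genes by the same kind of test, although both lines carry Otx2. Single genes that stood out in the Otx2-/- interaction were AA467197, with a difference of 5.70, and BC017158, with 5.23. Both had their high value in the lone Otx2-/- EpiLC library, so no second library of that state bears on them.

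Most calls in the Otx2-/- comparisons were small RNAs, 15 of 20 in EpiLC and 11 of 17 in ESC. Values that are unstable in single libraries are a candidate explanation. Otx2-/- EpiLC lifted 15 small RNAs at least 4-fold above all other non-transgenic libraries and Otx2-/- ESC 11, within the 9 to 17 that single R1 and E14 libraries lifted. Loss of Otx2 as the cause cannot be told apart from this: 0 further libraries of the same state lacked Otx2, since the uninduced transgenic ESCs had it at 45.8 FPKM, above the 9.09 of the highest R1 or E14 ESC library.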

How the results depend on the processing

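Results without small RNAs and entries listed at 0, and list counts without R1 ESC replicate 1, were chosen after seeing the data; the other alternatives were planned. Of the counts and medians, 155 alternatives gave a similar value (within 1.5 times) and 71 moved. For named genes, 3212 kept their direction and side of the threshold (or stayed within the spread of 0.461 for untested ratios), 202 were no longer called, 3 became called, 221 untested ratios moved and 1 turned: Pou3f1 in Otx2-/- ESC, not called in either fit, went from -0.26 to 0.15 with the uninduced transgenic library added. All 13 camera calls were lost with an estimated correlation, and the 102 camera results that stayed on their side were lists not called in either setting. Fry, which tests a list against no change and not against other genes, called the same 5 lists as camera in EpiLC against ESC, but none of the 2 lists that camera called in Otx2-/- EpiLC, the 3 in Otx2-/- ESC and the 3 in E14 minus R1. In EpiLC against ESC, a mean of at least 5 FPKM gave 672 genes higher, R1 alone 515 higher and 366 lower, and leaving out each library gave between 211 and 1890 higher and between 187 and 2228 lower; fewer libraries leave fewer degrees of freedom. In Otx2-/- EpiLC against R1 and E14 EpiLC, no filter gave 53 higher and 6 lower, leaving out small RNAs and entries listed at 0 gave 2 and 1, and the lower calls ranged from 2 to 21 with each library left out. In Otx2-/- ESC, 29 were higher with no filter, 29 in a fit of ESC libraries alone and 0 at a mean of 5 FPKM, 11 were lower with a pseudocount of 0.1, and 0 were higher and 0 lower either with the uninduced transgenic library added or without small RNAs and entries listed at 0; left-out libraries gave between 13 and 20 higher and between 5 and 10 lower. For the Otx2-/- response minus that of R1 and E14, the higher and lower calls were 10 and 2 with a pseudocount of 0.1, 6 and 2 at a mean of 5 FPKM, 14 and 2 with the uninduced library added, 2 and 0 without small RNAs and entries listed at 0, and between 10 and 26 and between 0 and 26 with libraries left out. For E14 minus R1 they were 5 and 12 with a pseudocount of 0.1, 6 and 7 at a mean of 5 FPKM, 0 and 0 without small RNAs and entries listed at 0, and between 0 and 47 and between 0 and 80 with libraries left out. In single pairs, a log2 ratio of at least 2 counted 117 genes for activin A, 346 for dox, 138 for the uninduced line against Otx2-/- ESC, 533 for E14, 485 for Otx2-/- differentiation and 206 for the R1 ESC replicates, as a stricter rule must. A pseudocount of 5 gave 669 for dox, 942 for E14, 909 for Otx2-/- differentiation and 593 for the R1 ESC replicates, and leaving out small RNAs and entries listed at 0 gave 52 for activin A and 85 for the uninduced line. Genes called by 2-fold or more, with a mean of at least 1 FPKM in the pair, had dox medians of 0.50 (higher) and -0.63 (lower). In the uninduced line against Otx2-/- ESC the higher ones had 0.13. For the other changes the cause was not tested. Taking the highest entry per symbol in place of the sum changed 26 symbols, 2 of them with a mean of at least 1 FPKM, and says nothing about stability. The count-based alternatives were not run, because the tables hold FPKM. No paired analysis was possible because the groups share only replicate number 1, given in accession order. Depth limits low genes most in E14 EpiLC, where 1 fragment in 1 kb is worth 0.16 FPKM, and least in Otx2-/- ESC, at 0.048.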

Other observations

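The tests chosen only after the result was seen were the count over other splits of the libraries, the depth comparison for R1 ESC replicate 1, the correlation over its 880 differing genes with the genes named there, and the treatment of dox itself as an explanation. Comparing 3 ESC pairs in the test of variation between cultures was likewise added later.

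Zscan4 genes, markers of a 2-cell-like state, were higher in all 3 ESC libraries of Otx2-/- origin. Zscan4c had 9.26 FPKM in Otx2-/- ESC, 11.7 in the transgenic line without dox and 23.3 with dox, against 1.22 and 3.19 in the R1 ESC replicates and 2.18 in E14 ESC. On conversion of Otx2-/- cells it went to 2.41 FPKM. The copies share reads, so single members are uncertain, and differences between lines other than Otx2 were not separated.

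Of the 6 libraries of R1 and E14, only 1 of 10 splits into 3 and 3, the real one, gave as many calls as the 2484 observed, and the highest of the others gave 40. These are too few splits for a share under 0.05.

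R1 ESC replicate 1 differed from replicate 2 in 880 genes without small RNAs and entries listed at 0. Lower depth argues poorly for this, since E14 ESC, of about the same depth, differed from replicate 2 in 66 genes. The trend on transcript length and GC content was small, at most 0.26 on the log2 scale. It was taken over the 90.0% of genes with a matched transcript length, of which 806 passed the size rule. After centring 780 of them passed, and 764 once the trend was removed (64 left and 48 came in). Pairs of other ESC libraries differed in at most 153 genes, counted without centring or a length match. Partial differentiation stays open: replicate 1 minus replicate 2 correlated with the E14 differentiation change at r = 0.03 and with the Otx2-/- change at 0.072 over 11936 genes, which dilute the pattern, but at 0.157 and 0.239 over the 880. Dnmt3b (77.1 against 28.6 FPKM) and Grhl2 (4.43 against 0.868) were higher in replicate 1, Car4 (0.122 against 0.211) and Pou3f1 (0.921 against 1.66) were not, and batch was not tested, as the labels give none.

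Of the genes called in R1 and E14 EpiLC, 69.1% of the higher and 73.6% of the lower ones went the same way with dox. Variation between ESC cultures argues poorly for this: for 425 higher and 543 lower genes chosen in E14 and Otx2-/- differentiation, the gap between medians was 0.99 with dox, 0.11 between the R1 ESC replicates and at most 0.19 over 3 pairs of ESC libraries. Whether the lower depth with dox accounts for part of the higher genes was not decided. The 221 of them with a mean of at least 20 FPKM had a median of 0.12, while the 503 lower ones kept -0.36. The 0.33 over the called higher genes leaves out those with a mean under 1 FPKM in the pair, so the gene sets compared were chosen by different rules. Dox itself cannot be told apart from Otx2, because 0 libraries had dox without the transgene. An action of Otx2 on part of the EpiLC programme, in ESC medium, is a hypothesis that these libraries leave open. The uninduced line had Otx2 at 45.8 FPKM. Against Otx2-/- ESC, its called higher genes had a median of 0.06 (percentile 99.99) and the lower ones 0.01 (percentile 2.09). Those called by 2-fold or more had 0.13 (percentile 100) and -0.02 (percentile 0). These shifts were small, but relative to matched genes they lay in the EpiLC direction. Dox without the transgene, and replicated induction to the EpiLC mean of 99.1 FPKM in place of 1059.3, would test the hypothesis.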
